A study of Homo sapiens with 22 samples.

How the data were processed

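RNA was measured in 22 samples of bioprinted human liver tissue, a printed 3-dimensional co-culture of cryopreserved primary hepatocytes with stellate, endothelial and Kupffer cells on inserts. Per the labels' protocols, tissues matured for 3 days, and the MASH group then received oleic and palmitic acid at 3 mM in total with 10 ug/mL lipopolysaccharide and 10% bovine serum albumin. MASH is metabolic dysfunction-associated steatohepatitis, the inflamed form of fatty liver disease. Healthy tissues were kept without that mixture. Libraries were polyA-selected and strand-specific, per the labels' protocols.

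The authors deposited 1 table of expected counts per gene, not scaled between libraries. Per the submitters' processing notes the tools were FastQC 0.11.8, STAR and RSEM on GRCh38.p13. The versions of STAR and RSEM and the annotation release are not given in the sources used here. RSEM shares reads between similar transcripts, so counts of near-identical paralogs and of overlapping genes carry uncertainty that the table does not state. Expected counts were rounded to whole numbers before testing. The table has 16777 rows, each with a gene symbol, and 1 column that matched no sample was not used.

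Samples were grouped by disease stage and day from their titles. The third healthy day 7 library carries a day 14 tag in another label and was kept at day 7 by its title. Titles of 11 libraries, the 10 healthy ones and MASH day 21 replicate N, end in a number (numeric-suffix set). The trailing number of their columns differs from that of their titles, so these columns were matched by day and replicate code, which no other title has. Titles of the other 11 MASH libraries end in S and a number (S-suffix set). The set therefore separates MASH from healthy in all but 1 library, and the labels do not say what the set stands for. No label states that replicates came from separate donors or cultures, so p-values measure only the spread between these libraries, which may be technical. No pair of replicates agreed within sampling noise, and the lowest chi-square per degree of freedom between replicates was 6.05.

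The row order was checked by correlating the mean log2(CPM + 1) of the 2 sets over sliding windows of 50 rows. The first 3255 rows (19.4%) matched in every window. No window that starts in the 13522 rows after them reached the minimum correlation of 0.9. The window that starts at row 3255 still matched, so the mismatch begins within 50 rows after that row and the cut is early. From there on the values of 1 set do not belong to the gene symbols printed beside them. Ribosomal protein genes after row 3255 had a median of 1816.71 CPM in the S-suffix set and 8.32 CPM in the numeric-suffix set. The numeric-suffix columns are therefore the displaced ones. No row was moved or relabelled. Every comparison that involves a healthy library or replicate N was limited to the first 3255 rows, and this departs from the planned use of all rows. CPM in these comparisons is taken over the counts of those rows, on library sizes scaled by TMM. A fit to all rows of the 11 S-suffix MASH libraries was added after the data had been seen, with CPM over the counts of the whole table.

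Total counts were 12.5 M to 17 M per numeric-suffix library and 22.3 M to 31.5 M per S-suffix library. In the first 3255 rows they were 3.54 M to 4.73 M and 5.11 M to 8.36 M. A count of 3, the floor used for groups at 0, was worth 0.63 to 0.85 CPM and 0.36 to 0.59 CPM of those rows. Floors cover the error of read counts only. Intervals of a share of genes treat genes as independent and do not cover the spread between libraries.

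Genes were kept by filterByExpr with a minimum count of 10, which left 2858 genes, and 12462 in the whole-table fit. Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, a mean for each of the 8 groups, all 22 libraries sharing 1 estimate of spread, and the robust quasi-likelihood F test. The common dispersion was 0.0198. The contrasts were MASH minus healthy on each day and as the mean of the 4 days, day 21 minus day 1 in each arm, and the difference of those changes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and genes of at least 2-fold change were counted beside them. The adjusted p-values of genes come from this test. A share of genes carries a 95% Clopper-Pearson interval.

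The groups, contrasts, tests, rule for named genes, 31 gene lists and most alternatives were fixed before the data were examined. Among called genes with a mean log2 CPM of at least 3, the rule named the 10 largest changes each way with the same sign on all 4 days, the 3 largest each way per day, and the 5 largest each way for the day 21 minus day 1 changes and their difference. In the whole-table fit it named 10 each way. In each list the members with the smallest adjusted p were named, 4 at most, and in cell type lists also those with the highest mean CPM. Genes that can tell donors apart were never named. The lists were written from textbook knowledge of liver metabolism, inflammation, stress responses, fibrosis and cell types. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists tested. Camera with an estimated correlation and fry were run beside it. In the restricted rows 12 lists could be tested, and 29 in the whole table.

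Alternatives were DESeq2 1.42.0 size factors and Wald test, upper-quartile factors, TMM without the 50 genes with the most counts, no filter, at least 1 CPM in at least 10 libraries, limma-voom with quality weights, both treatments of the library with conflicting day labels, the title set as a covariate, only numeric-suffix libraries, only the groups compared, a replicate block, and each library left out. All rows at face value, library sizes from all rows, S-suffix libraries thinned to the numeric-suffix depth, and means over fewer days were added after the data had been seen. The pipeline was tested on simulated counts of the 2858 genes. For the mean of 4 days it recovered 89.6% of genes changed 1.5-fold and 94% of those changed 2-fold, and for day 1 it recovered 34.3% and 83.6%. It made 7 false calls among the other genes for the mean of 4 days and 5 for day 1. With no simulated difference between the arms' changes, it called 0 genes. No difference between the title sets was simulated, so these figures do not show how the pipeline handles one.

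Gene positions are from GENCODE release 29 on GRCh38, matched by gene identifier, and 241 of 241 named genes matched. Some genes are not analysed here, among them list members without a row in the table, and a few named by the rule or in the lists are not reported here.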

Results

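Gene expression was profiled in bioprinted human liver tissues that were either kept healthy or driven towards MASH with fatty acids and lipopolysaccharide, a bacterial endotoxin. The healthy arm held 2, 3, 3 and 2 libraries at days 1, 7, 14 and 21, and the MASH arm held 2, 3, 3 and 4. The design sets the treated tissues against the untreated ones over time, for later comparison with published studies of human MASH liver. Total counts ran from 12.5 M to 17 M in the 11 libraries of the numeric-suffix set and from 22.3 M to 31.5 M in the 11 of the S-suffix set. In a principal component analysis of the tested genes, the first component held 38% of the variance and the second 20.2%. On the second the S-suffix libraries lay from 3.418 to 22.73, and all numeric-suffix libraries after day 1 were below 0, MASH day 21 replicate N (-3.5) among them; the healthy day 1 libraries lay at 2.934 and 7.87.

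Only part of the table could be used to compare the arms. Over the first 3255 of 16777 rows the mean log2 levels of the 2 sets correlated across genes at r = 0.991. Over the remaining rows r was 0.159, and beyond the first of them rows labelled with the same gene held unrelated values. Of the 58 ribosomal protein genes in those rows, none was under 1 CPM in the S-suffix libraries and 19 were under 1 CPM in the numeric-suffix libraries. MASH day 21 replicate N, the only MASH library in the numeric-suffix set, correlated there at r = 0.154 with each other MASH day 21 library and at 0.991 and 0.989 with the 2 healthy day 21 libraries. Comparisons with healthy tissue therefore cover 2858 tested genes in the first rows, and genes such as ALB and COL3A1 could be followed only within the S-suffix MASH libraries.

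**Figure D1:**
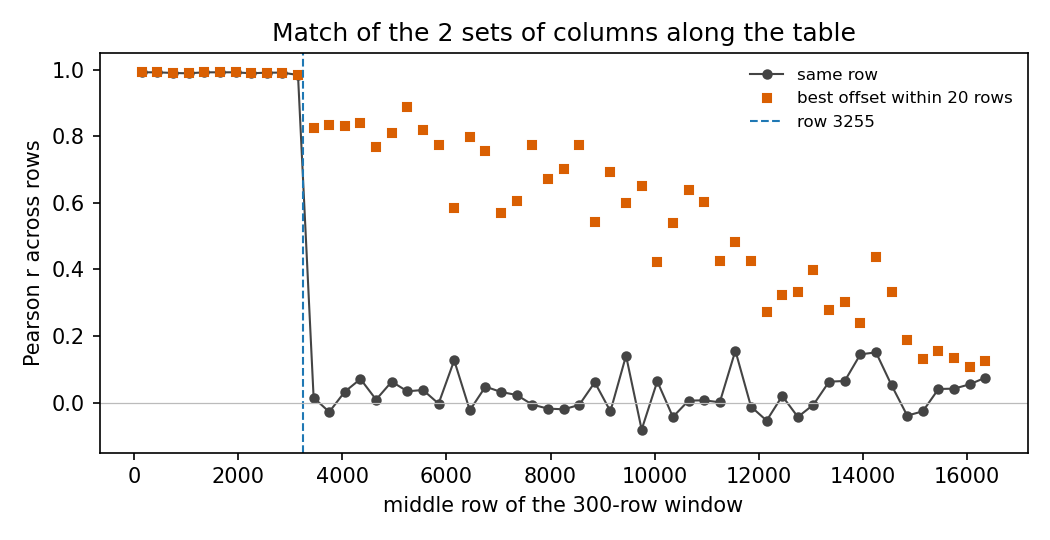
Pearson correlation across rows (y axis) between the mean log2(CPM + 1) of the 11 numeric-suffix and the 11 S-suffix libraries, in windows of 300 rows along the deposited table (x axis, middle row of the window). Grey points compare the same row and orange squares the best offset within 20 rows. The match at the same row is at least 0.989 in the 10 windows before row 3255 (dashed line). It is 0.984 in the window of rows 3001 to 3300, which spans that row, and is lost in the windows after that.

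MASH tissues differed from healthy ones in 1431 of 2858 tested genes when the 4 days were averaged. ODAM, a secreted epithelial protein (ENSG00000109205, chromosome 4, 70196496 to 70204576), was 4.78-fold higher in MASH (log2 fold change 2.26, SE 0.16, adjusted p = 7.9e-10, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). At day 21 its level was 108 ± 32.6 CPM (SD, n = 4) in MASH and 16.1 ± 2.33 CPM (n = 2) in healthy tissue. The chitinase-like gene CHI3L2 (chromosome 1, 111200771 to 111243440) was 4.29-fold higher, the retinol dehydrogenase gene DHRS9 4.35-fold and APOA4, an apolipoprotein, 4.2-fold. PHGDH, the first enzyme of serine synthesis, rose 2.32-fold. DGAT2, which makes triglyceride from diacylglycerol (chromosome 11, 75759512 to 75801535), rose 2.26-fold, and MLYCD, which degrades malonyl-CoA, 2.2-fold. HTR2A, CDH19 and ADGRF5 had log2 fold changes of 1.40, 1.21 and 1.16. They completed the 10 largest increases among called genes with the same sign on all 4 days and a mean log2 CPM of at least 3.

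The largest decreases among the named genes were those of CEMIP and COMP. CEMIP, a hyaluronan-degrading protein (chromosome 15, 80779343 to 80951776), was 9.51-fold lower (log2 fold change -3.25, SE 0.24, adjusted p = 1.5e-08, edgeR), and the matrix protein COMP was 8.76-fold lower (log2 fold change -3.13; -2.29 and not called, adjusted p = 0.135, without healthy day 1 replicate 2). CEMIP stood at 710 ± 359 CPM in healthy and 28 ± 5.2 CPM in MASH tissue at day 14 (n = 3 each). SERTAD4 was 4.34-fold lower, LIMS2 3.77-fold and SEC31B 3.2-fold. The cytokine IL11 was 3.02-fold lower and the hyaluronan synthase HAS1 3-fold lower. HAS1 rested on 14 counts over the MASH day 14 libraries and 16 over the MASH day 21 libraries. PABPC1L, HSF4 and GSDMB were 2.71-fold, 2.66-fold and 2.61-fold lower. In all, 699 genes were higher and 732 lower of 2858 tested, with 33 and 77 of them changed at least 2-fold.

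With the set as a covariate the 1431 calls fell to 94, of which 69 had been called in the same direction without it. Only MASH day 21 holds both sets, so the set term rests on 1 library, replicate N against replicates A to C. That day 21 difference is then subtracted at every day. Calls kept or lost under the covariate therefore do not separate the set from the treatment. ODAM (log2 fold change 2.19, adjusted p = 0.000438), CHI3L2, PHGDH, DGAT2, COMP, SERTAD4 and LIMS2 stayed called. Other calls ended with the log2 fold change closer to 0, at 0.871 for DHRS9, 0.531 for CDH19, 0.297 for MLYCD, -0.215 for SEC31B, -0.185 for PABPC1L, -0.147 for HSF4 and -0.233 for GSDMB. CEMIP (-1.93, SE 0.735, adjusted p = 0.172), APOA4 (2.06), HTR2A (1.06), ADGRF5 (1.26), IL11 (-1.41) and HAS1 (-2.05) kept changes of at least 2-fold and were not called.

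**Figure D2:**
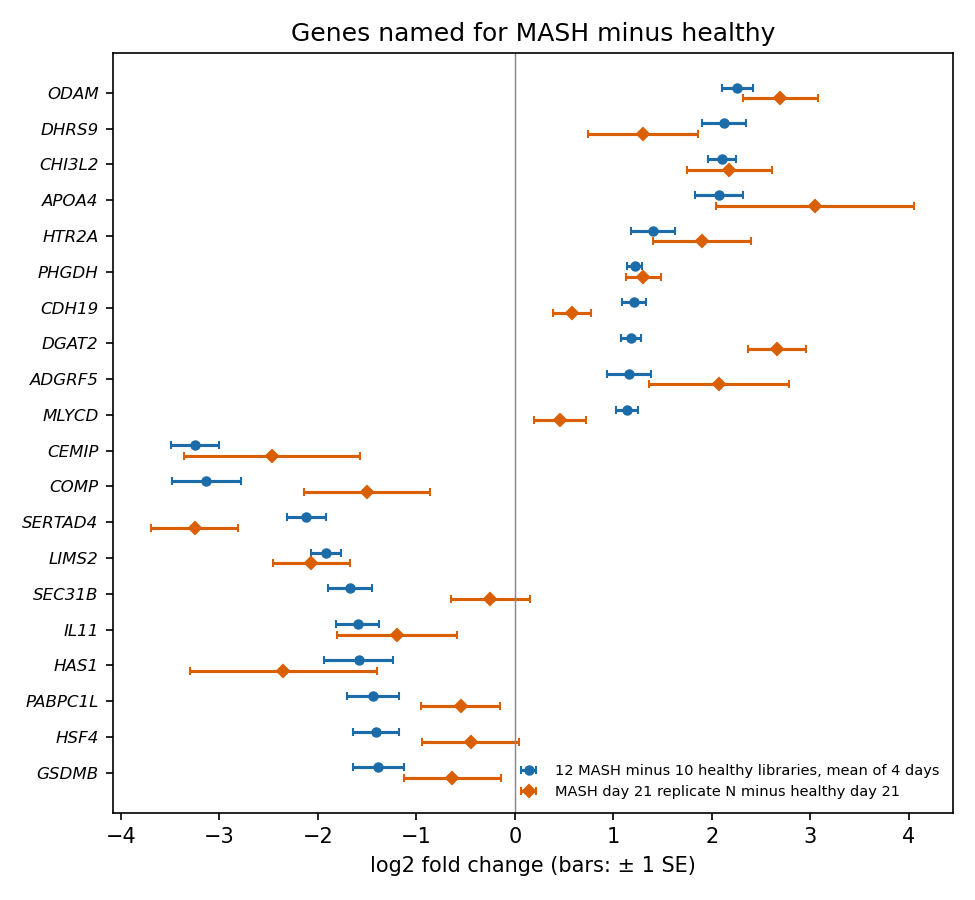
Log2 fold change with bars of 1 SE (x axis) for the 20 genes that the rule named for the mean of 4 days (y axis). Blue circles show 12 MASH minus 10 healthy libraries as the mean of 4 days. Orange diamonds show MASH day 21 replicate N minus the 2 healthy day 21 libraries. The libraries behind the orange values are part of the blue ones, and the genes were chosen for the same sign on all 4 days, so a shared sign is no separate evidence; SEC31B lies nearest to 0 in replicate N at -0.25.

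Among the fixed gene lists, the bile acid list was higher in MASH, with 4 of its 7 tested members raised and none lowered, and 4 raised when adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.0855 with an estimated correlation). These were ABCC2, the canalicular pump for conjugated organic anions (log2 fold change 1.16), the bile acid receptor NR1H4 (2.11-fold), the bile acid importer SLC10A1 (log2 fold change 1.58, adjusted p = 0.027) and the bile salt export pump ABCB11 (1.47-fold). SLC10A1 rested on 3 to 9 counts per healthy group. Leaving out 1 library at a time ended the call of ABCB11 in 15 of 22 cases and that of SLC10A1 in 3, and SLC10A1 ran from 1.29 without MASH day 1 replicate A (adjusted p = 0.242) to 2.58 without healthy day 14 replicate 2. In the list of PPAR-alpha targets and fatty acid oxidation, PDK4, which restrains pyruvate oxidation, and HADHA, of mitochondrial beta-oxidation, rose 2.06-fold and 1.93-fold, while CREB3L3 was lower, 3 of 6 members were not called, and the list did not pass (camera p 0.0125, adjusted p = 0.05; 0.0906 as adjusted p with an estimated correlation). Of 6 fatty acid and triglyceride synthesis genes, DGAT2, SCD and ELOVL5 were higher and SREBF1 and MLXIPL lower, and the list was not called (camera adjusted p = 0.291). MLXIPL had 7 counts in healthy and 8 in MASH tissue at day 21, and leaving out 1 library ended its call in 5 of 22 cases. With the set as a covariate ABCC2 (log2 fold change 1.5), PDK4 (0.96) and SCD (1.2) stayed called. NR1H4 (0.09), HADHA (0.353), SLC10A1 (0.631) and ABCB11 (0.567) did not, and CREB3L3, ELOVL5, SREBF1 and MLXIPL changed sign. The bile acid list was then not called (camera adjusted p = 0.212). PPAR-alpha targets were called higher (0.000662; adjusted p = 0.014 with an estimated correlation), as was fatty acid and triglyceride synthesis (0.00596; adjusted p = 0.179 with an estimated correlation). PPAR-alpha targets were also called with DESeq2 size factors (0.0498; adjusted p = 0.0903 with an estimated correlation) and without the library of conflicting day labels (0.0344; adjusted p = 0.0736 with an estimated correlation).

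The list of genes reported as raised in fibrotic MASH liver was lower in these MASH tissues, with 5 of 6 tested members lower and 1 higher, and the same 5 and 1 adjusted over the list alone (camera adjusted p = 0.033; adjusted p = 0.0855 with an estimated correlation). AEBP1, a matrix-associated transcription factor, was 1.95-fold lower, COL1A1, the main fibrillar collagen chain, 1.72-fold lower, and TNFRSF12A and CD9 were 1.26-fold and 1.19-fold lower. STMN2 was lower by a log2 fold change of -0.88, and IL32 was higher by 0.28. The IL32 call ended in 15 of 22 cases with 1 library left out (0.17 without healthy day 21 replicate 1), and that of STMN2 ended without healthy day 1 replicate 2 (adjusted p = 0.0864). Within matrix remodelling, 3 of 6 members were lower, TGFB1 and MMP2 among them, and 3 were not called (camera adjusted p = 0.387). With the set as a covariate, COL1A1, TGFB1 and MMP2 changed sign, to 0.20, 0.23 and 0.10, and AEBP1 had -0.24. The list of genes raised in fibrotic MASH was then not called (camera adjusted p = 0.132). CD9 stayed called at -0.60 (adjusted p = 0.0334, edgeR), and TNFRSF12A (-0.578), STMN2 (-1.15) and IL32 (0.102) did not.

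Cell type and inflammation genes in the tested rows were few. The other 7 lists tested, those of hepatocyte secreted proteins, Kupffer cells, cholesterol synthesis, gluconeogenesis, the unfolded protein response, NRF2 and the cell cycle, were not called (camera adjusted p from 0.289 to 0.754). Of 4 stellate markers, VIM was higher and MYL9 lower, of 3 endothelial markers STAB1 was lower, and of 5 Kupffer cell markers MSR1 was lower. All 3 ribosomal protein genes were higher in MASH (RPL3 1.63-fold, RPLP0 1.56-fold, RPL18 1.3-fold). With the set as a covariate STAB1, RPLP0 and RPL18 changed sign and RPL3 had 0.08. VIM (0.296), MYL9 (-0.339) and MSR1 (-1.41) lost their calls with it. MSR1 went from -0.718 to -0.584 without healthy day 1 replicate 2. Of 3 cytokines, IL11 and CSF3 were lower, and CXCL2 was not called (2 lower by the test over all genes and 3 adjusted over the list alone). ICAM1 was 1.72-fold lower and BIRC3 1.64-fold higher, and both changed sign with the set as a covariate. The interferon-stimulated genes OAS2 and OAS1 were 1.58-fold and 1.55-fold higher. OAS2 stayed called with the set as a covariate (1.22, adjusted p = 0.00132, edgeR), as did the drug-metabolising CYP3A5, at -1.16 without and -1.46 with it. OAS1 (0.495) and CSF3 (-1.07) did not stay called.

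By day, 31 genes differed at day 1, 795 at day 7, 933 at day 14 and 466 at day 21 (edgeR). At day 1, DHRS9, PHGDH and CHI3L2 were the largest increases, 4.48-fold, 2.58-fold and 2.49-fold. HMOX1, the haem-degrading enzyme induced by oxidative stress, was the largest decrease, at 2140 ± 443 CPM in healthy and 652 ± 95.1 CPM in MASH tissue (n = 2 each), followed by IL11 and PRDM1. Leaving out 1 library at a time ended the day 1 call of DHRS9 in 18 of 22 cases and that of CHI3L2 in 12, with CHI3L2 at 0.812 without healthy day 1 replicate 1 and 2.13 without replicate 2. It ended those of IL11 and PRDM1 in 3 cases each, with IL11 at -1.22 and PRDM1 at -1.07 without healthy day 1 replicate 2. At day 7, ODAM, DHRS9 and CDH19 were 6.55-fold, 5.49-fold and 4.12-fold higher. DHRS9 rested on 14 counts over the healthy day 1 libraries and 16 over the healthy day 7 libraries. COMP, CEMIP and MYBL2, a cell cycle transcription factor, were 30.9-fold, 18.2-fold and 7.77-fold lower at day 7. At day 14, AMPH was 8.82-fold and APOA4 7.47-fold higher, and COMP, CEMIP and SERTAD4 33.8-fold, 25.2-fold and 8.28-fold lower. MMP9 had 0 counts in all 3 healthy day 14 libraries and 1.49 ± 1.08 CPM in MASH (n = 3), at least 1.89-fold higher against a floor of 3 counts per library. With the library of conflicting day labels placed at day 14, its sign turned to -0.62. At day 21, SEMA3G, AMPH and COL23A1 were 15.4-fold, 10.2-fold and 8.35-fold higher, and CEMIP, SERTAD4 and PTPRN 10.9-fold, 8.42-fold and 6.29-fold lower. SEMA3G ran from 3.26 to 4.95 on the log2 scale without healthy day 21 replicates 2 and 1, and PTPRN was not called without replicate 1 (adjusted p = 0.159).

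The day 14 and day 21 differences correlated across 2484 genes at r = 0.8, and day 1 with day 7 at 0.38; genes are not independent replicates. The same direction was called at days 7 and 14 in 532 genes, and at days 7, 14 and 21 in 229. Apart from replicate N, each day sets S-suffix against numeric-suffix libraries, so a constant set difference would also give such agreement. Day counts moved with single libraries. Day 1 had 3 calls without MASH day 1 replicate B and 110 without MASH day 21 replicate N. Day 7 had 454 calls without the library of conflicting day labels, and its 367 higher and 428 lower genes became 271 and 492 under upper-quartile scaling. The title set as a covariate gave 23 calls at day 1, 48 at day 7, 70 at day 14 and 220 at day 21. Of these, 6, 40, 60 and 140 had been called in the same direction without it. At day 21 the covariate leaves replicate N alone against healthy tissue, and at the other days it subtracts the day 21 difference between the sets. At day 1 PHGDH and HMOX1 stayed called, and DHRS9 (log2 fold change 0.861), CHI3L2 (0.571), IL11 (-1.42) and PRDM1 (-0.289) did not. At day 7 DHRS9 (1.15), CEMIP (-2.75) and MYBL2 (-2.88) lost their calls, at day 14 APOA4 (2.89), CEMIP (-3.23) and MMP9 (9.64, SE 3.61), and at day 21 CEMIP (-2.46) and PTPRN (-1.13, SE 0.935).

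At day 1, 6 lists were called at the preset correlation and none at an estimated one (adjusted p = 0.149 for 5 and 0.148 for 1). Those higher in MASH were hepatocyte secreted proteins (adjusted p = 0.0147), cholesterol synthesis (0.00725), fatty acid and triglyceride synthesis (0.0259), gluconeogenesis (0.0147) and the unfolded protein response (0.0127), and NRF2 targets were lower (0.0178). The bile acid list was called higher at day 14 (adjusted p = 0.00898; adjusted p = 0.0641 with an estimated correlation) and day 21 (0.0158; adjusted p = 0.0809 with an estimated correlation). The fibrotic MASH list was called lower at days 7, 14 and 21 (adjusted p = 0.0362, 0.0425 and 0.0426; 0.105, 0.0918 and 0.0809 as adjusted p with an estimated correlation). PPAR-alpha targets were called higher at day 21 (0.0426; adjusted p = 0.0809 with an estimated correlation).

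Both arms changed strongly between day 1 and day 21. In healthy tissue 493 genes rose and 468 fell, 227 and 173 of them at least 2-fold, and in MASH 680 rose and 622 fell, 277 and 213 at least 2-fold (edgeR). The flavin monooxygenase FMO2 (chromosome 1, 171185208 to 171211230) rose 103-fold in healthy tissue, from 13 ± 3.66 to 1341 ± 150 CPM (n = 2 each), and 111-fold in MASH. The small leucine-rich matrix protein ASPN rose 77.3-fold in healthy tissue and 248-fold in MASH. In healthy tissue its log2 fold change was 8.66 without day 1 replicate 1 and 5.42 without day 1 replicate 2, so the arms are not ranked by it. The nerve growth factor receptor NGFR, with 6 and 8 counts at day 1, rose 49.2-fold and 150-fold (log2 fold change in healthy tissue 5.62, and 7.17 and 4.89 without day 1 replicates 1 and 2). OGN and FMO1 had 2 counts each in healthy day 1 tissue and reached 188 ± 21.6 and 45.6 ± 0.122 CPM at day 21 (n = 2). MEST rose 137-fold in MASH, from 3.46 ± 2.2 (n = 2) to 506 ± 66.7 CPM (n = 4), a log2 fold change of 7.1, or 8.04 without day 1 replicate A.

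Among the genes that fell, the gelatinase MMP9 went from 56.4 ± 27.4 CPM in healthy day 1 tissue (n = 2) to 0 counts at day 21, at least 80.8-fold lower against a floor of 3 counts per library, and in MASH from 64.6 ± 9.14 CPM (n = 2) to 1 count over 4 libraries. IL11 was 55.6-fold lower in healthy tissue and 46.2-fold lower in MASH, and the granulocyte growth factor CSF3 47.2-fold and 33.5-fold. GALNT18 and HMOX1 were 41.6-fold and 30.6-fold lower in healthy tissue, GALNT18 on 7 counts at day 21, and PTPRN and CEMIP 221-fold and 50.6-fold lower in MASH. Without replicate N the log2 fold change of PTPRN went from -7.79 to -8.52. In healthy tissue CSF3 went from -5.56 to -6.38 without day 21 replicate 1 and GALNT18 from -5.38 to -5.98 without replicate 2, and in MASH IL11 went from -5.53 to -6.3 without day 21 replicate C.

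Fold changes over time correlated between the arms at r = 0.875 across 2484 genes with a mean log2 CPM of at least 3. In both arms 387 genes rose, against 117 expected from independent lists, 365 fell, against 102, and 4 were called in opposite directions. The arms share no library, and apart from replicate N each arm lies in 1 title set.

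**Figure D3:**
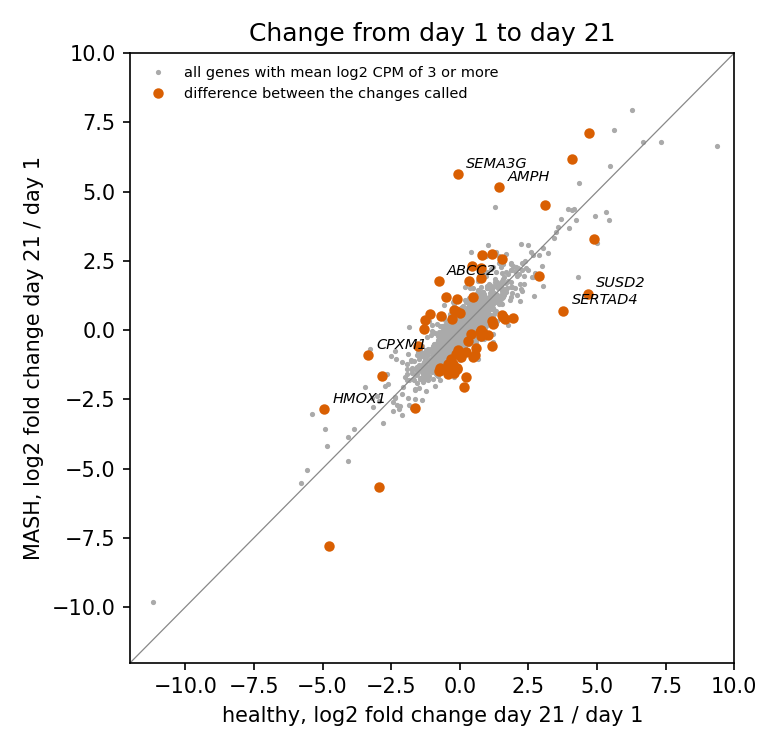
Log2 fold change from day 1 to day 21 in healthy (x axis) and MASH tissue (y axis) for 2482 genes with a mean log2 CPM of at least 3. Genes that can tell donors apart are not plotted. Grey points are the 2482 genes, the 68 orange points are those whose changes differed between the arms (edgeR, adjusted p under 0.05), and the line marks equal change.

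NRF2 targets, the antioxidant response genes, fell in both arms. Of 6 tested, 4 fell and none rose in each arm, also adjusted over the list alone (camera adjusted p = 5.97e-07 in healthy and 1.11e-05 in MASH; 0.00487 and 0.016 as adjusted p with an estimated correlation). GCLM and GCLC, the subunits of the rate-limiting enzyme of glutathione synthesis, were among them in both arms, and GCLM fell by 1.89 on the log2 scale in healthy tissue and by 2.44 in MASH. Matrix remodelling genes fell, 4 of 6 in healthy and 6 of 6 in MASH tissue, with TGFB1 at -0.94 and -1.12 (camera adjusted p = 9.93e-05 and 4.44e-06; 0.218 and 0.0806 as adjusted p with an estimated correlation). Unfolded protein response genes fell, 5 of 6 in each arm, with TRIB3 at -1.33 and -1.86 and the chaperone HSPA5 at -0.89 in both (camera adjusted p = 0.0115 and 0.00156; 0.271 and 0.0959 as adjusted p with an estimated correlation). Cell cycle genes fell in MASH, 4 of 5, with MCM2 at -1.12 (camera adjusted p = 0.0233; adjusted p = 0.0959 with an estimated correlation), and in healthy tissue 3 of 5 fell, 4 adjusted over the list alone, and the list was not called (0.121).

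Cholesterol synthesis genes rose in healthy tissue, 4 of 5 and 5 adjusted over the list alone, with MVK at 1.07 and MSMO1 at 0.75 (camera adjusted p = 0.0123; adjusted p = 0.271 with an estimated correlation). In MASH 1 of 5 rose and 1 fell (0.796). All 3 drug-metabolising genes tested rose in healthy tissue, among them SULT2A1 by 2.69 and CYP3A5 by 1.64 on the log2 scale, and SULT2A1 rose in MASH by 1.25. Of 4 stellate markers 3 rose in each arm. ACTA2, the smooth muscle actin of activated stellate cells, rose by 1.57 in healthy tissue and 0.48 in MASH, and DCN by 0.96 and 0.80. Leaving out 1 library ended the MASH call of ACTA2 (0.418 without day 1 replicate A) and the healthy call of DCN (0.74 without day 1 replicate 2) in 1 of 22 cases each. Of 3 endothelial markers 2 fell in healthy tissue and 1 in MASH, with the receptor TIE1 at -2.42 and -2.91. Of 5 Kupffer cell and macrophage markers 1 fell in each arm, the receptor MARCO, by 2.81 and 3.51, and 4 were not called. The healthy MARCO call rested on 11 counts at day 21 and ended without day 21 replicate 1 (adjusted p = 0.0599). The 3 ribosomal protein genes on the list rose in MASH (RPL18 0.79, RPLP0 0.69, RPL3 0.61), and none of the 3 was called in healthy tissue. The MASH calls of RPL3 (0.581 without day 1 replicate A) and RPLP0 (0.662 without day 1 replicate B) ended in 1 of 22 cases each. The other lists tested were not called, with camera adjusted p from 0.387 to 0.891 in healthy tissue apart from the cell cycle and from 0.0568 to 0.939 in MASH.

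The change over time differed between the arms in 70 genes, 30 with a higher change in MASH and 40 with a lower one (edgeR). SEMA3G, a secreted semaphorin of endothelial cells (chromosome 3, 52433053 to 52445085), rose from 0.814 ± 0.302 (n = 2) to 40.1 ± 6.53 CPM (n = 4) in MASH and stood at 2.71 ± 0.511 and 2.68 ± 2.02 CPM in healthy tissue (n = 2 each), a difference of 5.70 on the log2 scale (SE 0.93, adjusted p = 0.00119). AMPH differed by 3.71 and ABCC2 by 2.54, with ABCC2 at 86.9 ± 6.10 and 299 ± 40.1 CPM in MASH against 77.6 ± 30.5 and 45.6 ± 5.40 CPM in healthy tissue. CPXM1 and MEST differed by 2.46 and 2.40. SUSD2 rose 4.66 in healthy tissue and 1.31 in MASH, a difference of -3.34, and SERTAD4 differed by -3.07. PTPRN and CEMIP fell further in MASH, by differences of -3.03 and -2.73. TMEM176B fell by 2.05 in MASH and was not called in healthy tissue (0.158), a difference of -2.21. Leaving out 1 library at a time ended the call of the difference in 14 of 22 cases for PTPRN and in 9 for CEMIP. It ended it in 1 case each for AMPH (2.52 without healthy day 1 replicate 2), SERTAD4 (-2.42 without MASH day 1 replicate A) and MEST (2.06 without healthy day 1 replicate 1). SUSD2 moved to -2.67 without MASH day 1 replicate B, MEST to 3.33 without replicate A, and SEMA3G to 6.7 and 5.01 without healthy day 21 replicates 1 and 2.

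Among the 70, DGAT2 differed by 1.69 (adjusted p = 0.00365) and PDK4 by 1.01 (adjusted p = 0.0184). HMOX1 differed by 2.08, since it fell by 4.94 in healthy tissue and by 2.86 in MASH, and ACTA2 by -1.09. The call ended with 1 library left out in 1 of 22 cases for DGAT2 (1.19 without healthy day 1 replicate 2), in 4 for PDK4 and in 6 for MSMO1. Cholesterol synthesis was the only list called, lower in MASH, with MSMO1 at -0.81 passing the test over all genes and 5 of 5 members lower adjusted over the list alone (camera adjusted p = 0.000141; adjusted p = 0.201 with an estimated correlation). A constant difference between the title sets cancels from this contrast only where both days of an arm lie in 1 set. The count was 179 without replicate N, 27 without MASH day 1 replicate B, and 12 when only the 4 groups compared were fitted.

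The S-suffix MASH libraries allowed all rows to be followed from day 1 (n = 2) to day 21 (n = 3), a fit chosen after seeing the data and without healthy controls. Of 12462 genes, 3166 rose and 2964 fell, 1247 and 1010 at least 2-fold (edgeR). CD36, the fatty acid transporter (chromosome 7, 80369575 to 80679277), rose from 0.206 ± 0.125 to 555 ± 72.8 CPM (log2 fold change 11.47, SE 0.26, adjusted p = 1.6e-15), on 11 counts at day 1. Lipoprotein lipase LPL rose 289-fold, from 2.17 ± 0.986 to 603 ± 34.1 CPM, and the fatty acid binding protein FABP4 from 0.246 ± 0.307 to 180 ± 20.8 CPM. The alcohol dehydrogenase ADH1B rose 289-fold to 3101 ± 247 CPM, and SCARA5, CILP and ASPN 521-fold, 395-fold and 268-fold. CXCL13, a B cell chemokine, and INMT had 2 counts and 1 count at day 1 and stood at 64.7 ± 17.3 and 35.1 ± 7.89 CPM at day 21. Without MASH day 1 replicates A and B the log2 fold changes were 10.9 and 12.1 for CD36 and 8.59 and 12.4 for FABP4.

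**Figure D4:**
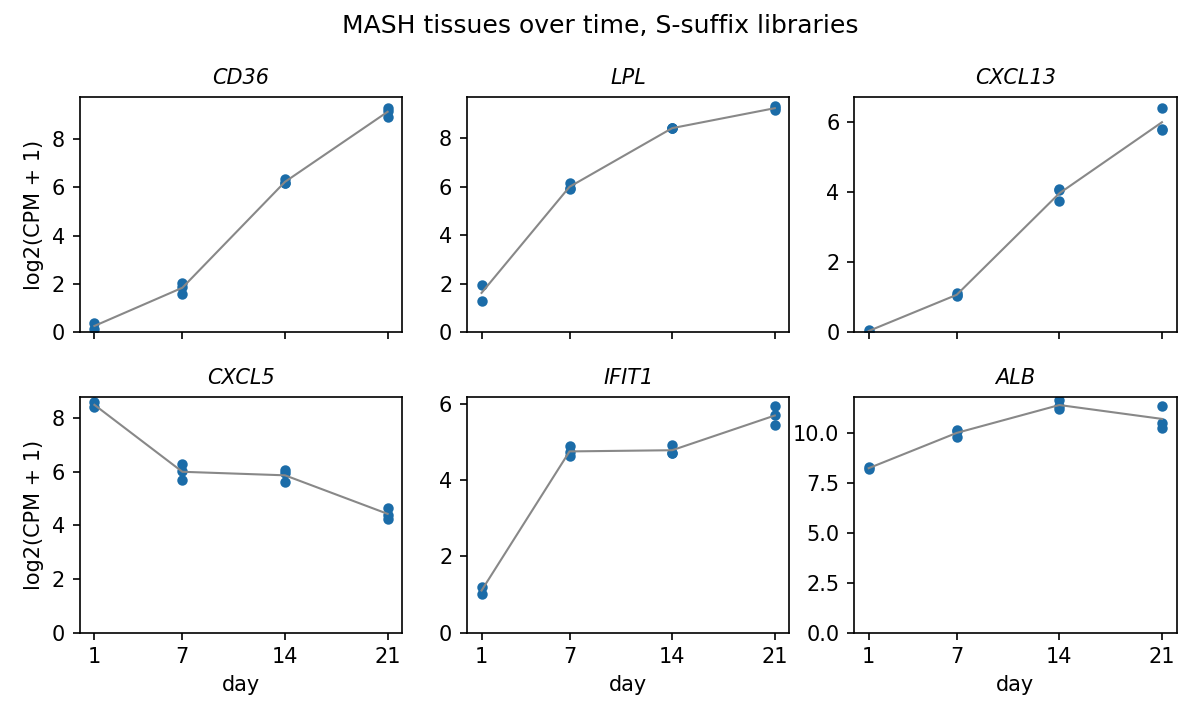
Log2(CPM + 1) of 6 genes (y axis) against day (x axis) in the 11 S-suffix MASH libraries. Points are single libraries (n = 2, 3, 3 and 3) and lines join the means; CD36, LPL, CXCL13 and IFIT1 were called higher and CXCL5 lower at day 21 than at day 1, and ALB had its highest mean at day 14.

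NF-kB cytokines and chemokines fell over the same time, while other inflammatory genes went both ways. All 15 on the list fell (camera adjusted p = 1.72e-15; adjusted p = 0.0671 with an estimated correlation). CXCL5 went from 361 ± 31 to 20.7 ± 3.17 CPM, LIF was 32.8-fold lower, CXCL3 23.1-fold and CSF3 36.9-fold, and IL1A fell by 4.77 on the log2 scale. PTGS2, the inducible cyclooxygenase, was 18.4-fold lower, IL24 39.8-fold, the metallothionein MT1G 26-fold, PTPRN 385-fold (10 counts at day 21) and CEMIP 72.3-fold. The log2 fold change of PTPRN went from -8.59 to -9.6 without day 21 replicate A and that of IL24 from -5.32 to -6.17 without replicate C. Among NF-kB feedback and adhesion genes 4 fell, led by ICAM1 (-2.77), and 3 rose, led by VCAM1 (2.42), of 9 (camera adjusted p = 0.184). Acute phase genes went both ways, 3 up and 6 down of 12, with SAA4 at 3.26, ORM1 at -2.10 and CRP at -2.08 (0.378). Of 13 interferon-stimulated genes 5 rose and 1 fell (camera adjusted p = 0.00789; adjusted p = 0.141 with an estimated correlation), IFIT1 from 1.15 ± 0.200 to 51.3 ± 9.06 CPM and IFIT2 and IFIT3 by 2.26 and 1.82. Immediate early genes fell, 10 of 14 with 1 higher, led by IER3 at -3.23 and JUNB at -1.88 (camera adjusted p = 8.77e-07; adjusted p = 0.116 with an estimated correlation).

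Matrix remodelling genes fell in 13 of 15 cases and rose in 2 (camera adjusted p = 8.38e-12; adjusted p = 0.0671 with an estimated correlation). The collagenase MMP1 went from 494 ± 6.65 to 5.85 ± 3.62 CPM, and TGFBI and LOX fell by 2.61 and 2.01 on the log2 scale. COL7A1, the anchoring fibril collagen, was 29.5-fold lower. Collagens and other structural matrix genes had 4 of 12 higher and 2 lower (camera adjusted p = 0.65), and COL1A1 stood at 6534 ± 984 and 6791 ± 690 CPM. Stellate markers rose in 9 of 15 and fell in 1 (camera adjusted p = 0.00989; adjusted p = 0.116 with an estimated correlation), with LUM at 2.25, PDGFRB at 1.55 and TAGLN at -1.04. Endothelial markers fell in 7 of 10 (camera adjusted p = 0.000129; adjusted p = 0.0671 with an estimated correlation), TIE1 by 2.86, TEK by 2.30 and EGFL7 by 1.63. Of 10 Kupffer cell markers 5 fell, among them CD163 by 2.07 and CD68 by 1.40, and the list was not called (0.0648). Genes reported as raised in fibrotic MASH liver split into 7 higher and 8 lower of 20 (0.444).

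Hepatocyte genes did not move as 1 group. ALB, albumin, went from 300 ± 10.2 to 1752 ± 723 CPM (log2 fold change 2.55, adjusted p = 1.53e-05, edgeR), whereas APOA1 and SERPINA1 fell by 1.97 and 3.05. Of 17 hepatocyte secreted proteins 4 rose and 9 fell (camera adjusted p = 0.184), and of 12 hepatocyte transcription factors 1 rose and 5 fell (0.22). Drug-metabolising genes rose in 5 of 13 and fell in 3 (camera adjusted p = 0.00105; adjusted p = 0.0671 with an estimated correlation), ADH1B among those that rose. Bile acid genes rose in 6 of 15 and fell in 1 (camera adjusted p = 0.0135; adjusted p = 0.157 with an estimated correlation), led by the oxysterol hydroxylase CYP7B1, from 5.43 ± 1.14 to 113 ± 0.979 CPM, with ABCC2 at 1.62 and NR1H4 at 2.21. PPAR-alpha targets rose in 9 of 19 and fell in 2, with PDK4 at 2.51, the lipid droplet gene CIDEC at 3.87 and ANGPTL4 at -1.77, and the list was not called (0.0553). Fatty acid synthesis genes had 4 of 18 higher and 6 lower (0.806) and cholesterol synthesis 8 of 17 higher and 2 lower (0.184).

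Stress genes fell and translation and mitochondrial transcripts rose. NRF2 targets fell in 13 of 16 and rose in 1, with GCLM at -2.53, HMOX1 at -2.96 and MT2A at -2.96 (camera adjusted p = 1.43e-10; adjusted p = 0.0671 with an estimated correlation). Unfolded protein response genes fell in 11 of 15 (0.000724; adjusted p = 0.0805 with an estimated correlation), glycolysis and hypoxia genes in 8 of 12 (0.00105; adjusted p = 0.126 with an estimated correlation), and cell cycle genes in 10 of 17 (0.0151; adjusted p = 0.334 with an estimated correlation). All 13 mitochondrially encoded genes rose, MT-ND3 by 1.98 and MT-CO3 by 1.26 (camera adjusted p = 3.19e-08, and adjusted p = 0.116 with an estimated correlation). The 19 ribosomal protein genes on the list all rose (camera adjusted p = 5.3e-08, and adjusted p = 0.292 with an estimated correlation). Urea cycle genes had 5 of 15 higher and 4 lower (0.569), gluconeogenesis genes 4 of 12 higher and 2 lower (0.444), p53 targets 3 of 9 higher and 4 lower (0.924), cholangiocyte markers 1 of 8 lower (0.457), and MHC class II genes 3 of 5 higher and 1 lower (0.552). The only lymphocyte marker tested, IL7R, fell by 3.06, and no erythroid marker passed the filter.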

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

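The window, correlation, depth and title-set tests on the mean of 4 days were chosen after the result was seen. The regroupings of libraries and the check of the time difference in replicate N were chosen before.

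In 4 of 64 named genes checked 1 of the 4 MASH day 21 libraries stood apart, where chance gives about 1 in 20 for any of them. In 0 genes was it another library than replicate N. Its gap to the nearest library, as a share of the group's range, was 0.875 for SEC31B (log2 CPM 4.89 against 3.45), 0.886 for SEMA3G (4.94 against 5.42), 0.924 for ABCC2 (8.49 against 8.14) and 0.964 for TGFB1 (8.53 against 7.93), each past Dixon's 95% critical value. It is the only MASH library of the numeric-suffix set.

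Rows labelled as olfactory receptors after row 3255 held at least 100 CPM in the numeric-suffix columns in 21 of 378 cases, and all 378 were under 1 CPM in the S-suffix columns. This is part of a wider pattern, the loss of match between the 2 sets after row 3255. A preparation or sequencing difference would lower the correlation in all rows, but it was 0.991 before and 0.159 after that row. A displacement of the numeric-suffix values against the row labels was the explanation that met its prediction: 40 of 44 windows of 300 rows matched best at an offset of 1 to 3 rows and 0 at the same row, although only 25 of the 44 reached a correlation of 0.5 and the last windows hardly favoured any offset. The 10 healthy libraries alone also matched best at such an offset in 40 windows. They are 10 of the 11 numeric-suffix libraries and were again set against MASH libraries, so this repeats the first result and cannot exclude the MASH treatment. Replicate N, a MASH library, goes against the treatment. After row 3255 it correlated at 0.154 with each other MASH day 21 library and at 0.991 and 0.989 with the 2 healthy day 21 libraries. The treatment also cannot move values to other rows. How the displacement arose was not tested.

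For the 1431 differences between MASH and healthy in the mean of 4 days, a chance assignment of single libraries was excluded. Of 100 regroupings 1, the real one, gave as many calls. The highest other, in which 9 of the 10 libraries grouped as healthy were of the numeric-suffix set, gave 672. A chance difference between cultures could not be tested, since no label states that replicates came from separate ones. Depth was excluded, since 1365 calls were made again after thinning. Of 1465 genes called over days 1, 7 and 14, 48.1% (95% interval 45.5 to 50.6) had the same direction in replicate N minus healthy day 21, against 47.1% of genes not called, but this was 62.5% against 51.3% with healthy replicate 1 alone and 38.8% against 47.1% with replicate 2 alone. Of the 118 changed at least 2-fold 72.9% (63.9 to 80.7) had the same direction. Every comparison of the arms within a set, or of the sets within MASH, rests on replicate N. The set and the treatment therefore cannot be told apart. The shares above rest on this 1 MASH library, whose own spread could not be measured. At day 7 the real split gave 795 calls and the highest other 0, and at day 14 they gave 933 and 1. At each day 1 of 10 splits was as large, and 10 are too few for a share under 0.05.

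The change from day 1 to day 21 differed between the arms in 70 genes, by a test of the difference itself, among them SEMA3G (5.70), AMPH (3.71), ABCC2 (2.54), CPXM1 (2.46), MEST (2.40), SUSD2 (-3.34), SERTAD4 (-3.07), PTPRN (-3.03), CEMIP (-2.73) and TMEM176B (-2.21). If a set difference at day 21 made these calls, replicate N, in the same set as the healthy libraries, would not follow them. Of 179 genes called without replicate N, 157 (87.7%, 95% interval 82 to 92.1) had the same sign in replicate N minus healthy day 14, against 57% of genes not called. This met the bound set for excluding it, but the bound was wrong, since it rests on 1 library and sets day 21 against day 14, and time changes correlated between the arms at 0.875. A set difference present at day 21 and not at day 1 and a response to the treatment that grows with time therefore cannot be told apart.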

How the results depend on the processing

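All rows at face value, whole-table library sizes, thinning, means over fewer days and the whole-table fit were chosen after the data were seen; the other settings were planned. Of 6920 alternative values for 226 named results, 6668 kept direction and side of the threshold, 236 fell below it and 16 reversed; 211 results never reversed. Most, 4246, came from leaving out a library. Under the title set as a covariate 101 of 160 were the same, 46 fell below the threshold and 13 reversed. The 160 include changes from day 1 to day 21, where the covariate can do little in healthy tissue and only takes replicate N out in MASH. Of all calls for these changes, 960 of 961 in healthy tissue and 1227 of 1302 in MASH were made again. For the mean of 4 days 69 of 1431 were. In the difference of the arms' changes the covariate only takes replicate N out, which on its own gave 179 calls, and it removes no set difference at day 21. At day 21 it leaves replicate N against healthy tissue. The title set as a covariate gave 94 calls for the mean of 4 days, 48 at day 7, 70 at day 14, 220 at day 21 and 182 for the difference of the arms' changes. It reversed CREB3L3 (1.19), ELOVL5 (-0.0353), SREBF1 (0.307), MLXIPL (0.323), COL1A1 (0.198), TGFB1 (0.227), MMP2 (0.102), ICAM1 (0.116), BIRC3 (-0.524), RPLP0 (-0.051), RPL18 (-0.0229), STAB1 (0.723) and FDFT1 (-0.00959); the cause was not tested. Numeric-suffix libraries alone gave 119 calls at day 21, from fewer libraries. DESeq2's Wald test gave 93 at day 1 and 150 for the difference of changes, limma-voom 52 at day 1 and 1343 at day 7. Fits to only the groups compared gave 2 at day 1, 1250 at day 7, 101 at day 21 and 12 for the difference. The healthy library with conflicting day labels, placed at day 14, gave 12 calls at day 1 and 419 at day 7 and reversed MMP9 at day 14 (-0.619); left out, it gave 454 at day 7. It correlated at 0.987 and 0.985 with the other day 7 and at 0.981, 0.975 and 0.973 with the day 14 libraries. All rows at face value gave 12325, 9455, 11106, 11189 and 6594 calls for the mean and days 1, 7, 14 and 21, and 541 for the difference, by construction from displaced rows. The share of genes with the same direction in replicate N was 48.1%, 72.9% for changes of at least 2-fold, 62.5% against healthy day 21 replicate 1 alone and 38.8% against replicate 2 alone. Of the 12 gene lists, 2 were called by camera, 0 with an estimated correlation and 8 by fry. Camera called 3 with DESeq2 size factors and 3 without the library of conflicting day labels, PPAR-alpha targets being added each time, but 0 of them with an estimated correlation. With the title set as a covariate it called 2 others, fatty acid and triglyceride synthesis and PPAR-alpha targets, the latter also with an estimated correlation.

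Leaving out each library gave 1195 to 1614 calls for the mean of 4 days, 3 to 110 at day 1, 454 to 1047 at day 7, 567 to 1177 at day 14, 165 to 881 at day 21, 708 to 1118 and 935 to 1446 for the healthy and MASH changes over time, 27 to 179 for their difference, and 4666 to 6318 in the whole table. It ended the call of 26 of 225 called gene results, in 1 to 18 of 22 cases each: most for DHRS9 at day 1 (18), ABCB11 and IL32 in the mean of 4 days (15 each), the difference for PTPRN (14), CHI3L2 at day 1 (12) and the difference for CEMIP (9). COMP in the mean of 4 days had -2.29 without healthy day 1 replicate 2 and was not called. COL1A1 in the whole table, never called, ranged from -0.0916 without MASH day 1 A to 0.217 without MASH day 1 B, and was -0.0264 without MASH day 21 B. Without replicate N the counts were 110 at day 1, 881 at day 21 and 179 for the difference. Day 1 had 8 and 59 without healthy day 1 replicates 1 and 2, and 4 and 3 without MASH day 1 A and B. It had 18 and 15 without healthy day 7 replicates 1 and 2, 17 without healthy day 14 replicate 1 and MASH day 7 A and C, 16 without MASH day 14 A and C, and 18 and 59 without MASH day 21 B and C. Day 7 had 507 and 454 without healthy day 7 replicates 2 and 3 and 482 and 471 without MASH day 7 A and C. Day 14 had 614 and 582 without healthy day 14 replicates 1 and 2 and 567 without MASH day 14 B. Day 21 had 165 without healthy day 21 replicate 1. The difference had 42 without healthy day 1 replicate 1, 35 and 39 without healthy day 21 replicates 1 and 2, and 37 and 27 without MASH day 1 A and B. A group left with 1 library was assumed to vary like the others. Replicate labels shared only a name (mean correlation of same-label deviations -0.0291 in 13 healthy and -0.000975 in 15 MASH pairs), and a replicate block gave 1036, 1304 and 103 calls for the healthy and MASH changes and their difference and 5683 in the whole table. Numeric-suffix fits for the other MASH contrasts and a block across the arms were not run, since the arms share no labels and the set holds 1 MASH library. At this depth simulated 1.5-fold changes were recovered in 34.3% of genes at day 1 and 89.6% in the mean of 4 days.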

Other observations

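The whole-table test of day 7 against day 1 in MASH tissue was chosen after the data were seen. In the S-suffix MASH libraries 2459 of 12462 genes were higher and 2466 lower at day 7 than at day 1 (edgeR, n = 3 and 2). Unfolded protein response genes were lower in 13 of 15 cases (camera adjusted p = 1.62e-09; adjusted p = 0.0306 with an estimated correlation), cell cycle genes in 14 of 17 (3.95e-08; adjusted p = 0.0863 with an estimated correlation), and NF-kB cytokines and chemokines in 13 of 15 (1.55e-14; adjusted p = 0.0732 with an estimated correlation). NRF2 targets were lower in 10 of 16 and higher in 1 (1.15e-12; adjusted p = 0.0371 with an estimated correlation), and drug-metabolising genes were higher in 5 of 13 with none lower (7.46e-05; adjusted p = 0.0371 with an estimated correlation).

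Some levels kept moving after day 7. CD36 stood at 2.62 ± 0.562 CPM at day 7, 73.6 ± 5.66 at day 14 and 555 ± 72.8 at day 21 (n = 3 each), and CXCL13 at 1.11 ± 0.0640, 14.8 ± 1.94 and 64.7 ± 17.3 CPM. LIF, in contrast, stood at 1.26 ± 0.405, 2.48 ± 1.13 and 2.72 ± 1.36 CPM on those days, after 86.7 ± 7.31 CPM at day 1 (n = 2). APOA1 stood at 42.9 ± 1.31 CPM at day 1, 24.0 ± 2.84 at day 7, 37.8 ± 8.19 at day 14 and 11.0 ± 0.206 at day 21. LUM stood at 1051 ± 43.8, 2367 ± 200.5, 3087 ± 525.5 and 4997 ± 1313 CPM on those days. These later changes were not tested against day 7.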
